A study of Arvicanthis niloticus with 5 samples.

How the data were processed

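RNA of Nile rat (Arvicanthis niloticus) eyes was sequenced. The labels list 5 samples, numbered 1, 3, 5, 7 and 9, all wild type, all eye tissue and all in 1 group, so the design holds no comparison between groups. Per the labels' protocols, the library of the species was pooled from the RNA of 5 rats. The expression table has 1 column of values for the whole series and no column per sample. Whether it sums the 5 samples or holds 1 of them is not stated in the sources used here. The table is treated as 1 pool, with no replicate error, no test between animals and no p-value. The planned correlations between samples, list spread between samples, exact sign-flip tests and left-out-sample checks could not be computed for this reason, and levels and ratios with counting intervals took their place.

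Per the file headers, each row gives a transcript, its FPKM (fragments per kilobase of transcript per 1000000 mapped fragments), its fragment count and its length. The fragment column deposited by the authors holds estimated counts that need not be whole, not scaled for length or depth. Of the 124439 transcripts, 39.3% had a fractional estimated count, so fragments were divided between transcripts. How they were divided, and how the transcripts were assembled, is not given in the sources used here. Per the submitters' processing notes, Bowtie, a short-read aligner, was used. Its version and the genome build, if any, are not given in the sources used here, so no genomic coordinates are reported. The file header states 64967222 mapped fragments. The FPKM deposited by the authors was rebuilt within a relative tolerance of 1e-05 for all 124299 transcripts with a fragment, as the count divided by the length and by that stated total. The division is by the full transcript length, with no correction for fragment size.

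Names came from a deposited ortholog table that gives, per transcript, a mouse, rat and human name. A name was used if it was a symbol rather than an Ensembl or GenBank identifier, in the order mouse, rat, human, without regard to case. This named 15454 transcripts of 13982 genes, and 75.9% of these genes had a Nile rat RefSeq gene of the same symbol. On 2586 named transcripts the symbols differed between species. A second ortholog table holds Ensembl identifiers only. Its column headed mouse holds 13857 rat identifiers and its column headed rat 15994 mouse identifiers. It gives no symbols and was not used for names.

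The level of a gene was the sum of the FPKM of its transcripts. A sum is right for isoforms and too high where 1 mRNA was assembled in several pieces, which can affect the 1380 genes with 2 or more transcripts. Gene-level intervals are 95% gamma (Fay-Feuer) intervals for Poisson fragment counts, exact for a gene with 1 transcript, and log2 ratios carry 95% delta-method Poisson intervals. The interval of the median over pairs came from 1000 redraws of the fragments. All of these cover counting error only: they hold no variation between animals or libraries, and PCR copies are not independent molecules. Error from the division of fragments between transcripts is not held either. At this depth FPKM 1 on a transcript of 1000 nt rests on 65.0 fragments (95% interval 0.772 to 1.28 FPKM), and a count of 0 there allows up to 3 fragments, or 0.0462 FPKM.

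A gene counted as detected at FPKM of at least 1. Before the data were examined, 32 gene lists (cell types of the eye and adjoining tissue, pathways, quality sets) and 11 pairs of homologous cone and rod genes were fixed. Each list was given as a percent of the FPKM of all named genes. The median log2(FPKM + 1) of its detected members was placed among the medians of 10000 random lists of the same size drawn from the 13037 detected genes. This percentile describes the pool and is not a test over animals. It was given for lists with at least 3 detected members. The genes named are the 20 of highest FPKM, both members of each pair and Opn1sw, and the 2 highest members of each list. The part of the rule on the most variable genes could not be applied, and no symbol of the sex-linked list was found on a transcript. Some genes under this rule, and 1 of the measured pairs, are not reported here one by one but enter the counts, medians and sums. All further genes named as examples were chosen after their values were seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

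On simulated fragments drawn from the counts of the paired genes, 94.7% of the ratio intervals and 95.4% of the level intervals held the true value (1600 draws each). The draws were Poisson, as the intervals assume, so this checks the computation only. Among simulated lists of 12 genes drawn from the 13037 detected genes, 99.5% of those raised 4-fold and 7.0% of unchanged ones lay above 95% of random lists (200 draws each). The alternatives were other detection thresholds, a pseudocount of 1 in the ratios, rescaling to a sum of 1000000, the highest transcript per gene and other denominators. Added after the data were seen were a length-weighted mean over a gene's transcripts, only transcripts whose species symbols agree, a symbol taken from any species column, only transcripts of at least 500 nt, and fragments in place of FPKM in the list shares and in the lens to photoreceptor ratio.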

Results

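The transcriptome of the Nile rat eye was profiled by RNA sequencing. The Nile rat is a day-active African rodent, and the stated aim was to examine its ocular tissue. A single pool of 64967222 mapped fragments was quantified over 124439 transcripts of 100 to 12154 nt, with a median length of 388 nt and a median of 36 fragments. Of these, 15454 transcripts carried a gene symbol and stood for 13982 genes. All values below are from this 1 pool and have no replicate error, so intervals in brackets are 95% intervals for counting error alone.

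Lens genes were the most abundant named genes in the eye RNA. Of the 13982 named genes, 13037 (93.2%) reached FPKM 1, 8366 reached FPKM 5 and 309 reached FPKM 100, around a median of 6.50 FPKM. A gene was named only where a transcript of the same table carried its symbol, so these counts do not measure which part of the genome was expressed. Among the 20 genes of highest FPKM, 8 encoded crystallins, the refractive proteins of the lens. Crygb was highest at 3621 FPKM [3596 to 3646], followed by Cryab at 2894, Cryba4 at 2315, Crybb3 at 1802, Crygc at 1668, Cryba2 at 1410, Cryaa at 1263 and Crybb1 at 989.5 FPKM. Other lens genes in this set were Grifin, a lens galectin-related protein, at 1528 FPKM, Lgsn (lengsin) at 1063 FPKM and Bfsp1 (filensin, of the lens beaded filament) at 931 FPKM. Other members were the mitochondrial gene named cytochrome b (1392 FPKM), Fth1 (ferritin heavy chain, 1314 FPKM), Cst3 (cystatin C, 876 FPKM), Gapdh (849 FPKM), Apoe (apolipoprotein E, 818 FPKM), Rpl26 (787 FPKM), Tpt1 (746 FPKM) and a gene carrying the symbol Srprb. Srprb summed to 1332 FPKM over 2 transcripts, but the transcript that held 1307 FPKM of this was named Srprb in mouse and rat and TF (transferrin) in human, so its identity is uncertain. The 20 genes together held 11.98% of the FPKM of all named genes.

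Of the 32 fixed lists, 30 had at least 3 detected members. Of these, 15 had a median above that of at least 95% of random lists, against 1.5 by chance alone. A member counted as measured only where a transcript carried its symbol, which held for 346 of 453 members over the lists. Since 93.2% of all named genes reached FPKM 1, detection of all measured members of a list says little by itself. The lens crystallins had the highest median of any list, 1263 FPKM, and 13 of 13 measured members were above 10 FPKM. This median was the level of Cryaa, the sum of a 249 nt transcript at 1158 FPKM and a 676 nt transcript at 105 FPKM. Each was named from a different species, so the sum is too high if they are pieces of 1 mRNA. The crystallins held 7.22% [7.20 to 7.25] of the FPKM of all named genes. Members ranged from 14.4 FPKM for Crygn to 3621 FPKM for Crygb. The gamma crystallins are close paralogs, so the split of fragments among Cryga, Crygb, Crygc and Crygd is uncertain. Most crystallin transcripts were short, and with transcripts of under 500 nt left out the share was 2.47%. Counted as fragments, which are not divided by length, the crystallins held 1.73% of the fragments of named genes. Of the other lens genes, all 13 were detected, with a median of 59.0 FPKM. Besides Grifin and Lgsn, they included Bfsp2 (phakinin) at 319 FPKM, Lim2 at 253 FPKM and the lens water channel Mip at 194 FPKM. The lens transcription factors Foxe3 (7.92 FPKM) and Hsf4 (2.39 FPKM) lay below the median of this list, and Hsf4 was its lowest member.

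Photoreceptor genes were abundant as a class. All 20 genes common to rods and cones were detected, with a median of 95.3 FPKM, above that of all 10000 random lists. The highest were Unc119 (444 FPKM), the guanylate cyclase activator Guca1a (410 FPKM), phosducin (Pdc, 332 FPKM), the disc rim protein Prph2 (328 FPKM) and the retinoid carrier Rbp3 (305.5 FPKM). The lowest was Gucy2f, a retinal guanylate cyclase, at 1.54 FPKM. The transcription factors Otx2 and Crx stood at 115 and 91.8 FPKM. Of the rod list, whose median was 39.7 FPKM, 11 of 12 genes carried a symbol and all 11 were detected, with Gngt1 (502 FPKM) and Gnat1 (344 FPKM) among the highest. Sag, the rod arrestin, was carried by a single transcript of 1051 nt, named in mouse only, at 5.24 FPKM [4.71 to 5.82]. Any Sag transcript without a symbol would be missing from this level, so it was not read as low expression of the gene. Nrl and Nr2e3, transcription factors of the rod lineage, were at 13.1 and 41.8 FPKM. Of the cone list, whose median was 58.0 FPKM, 10 of 12 genes carried a symbol and all 10 were detected, with Opn1mw (162 FPKM) and Gnb3 (156 FPKM) highest and Thrb at 7.24 FPKM. The rod list held 1.26% of named FPKM and the cone list 0.285%. The shares depended on how transcripts of 1 gene were combined: with a length-weighted mean the rod list held 0.674%.

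**Figure D1:**
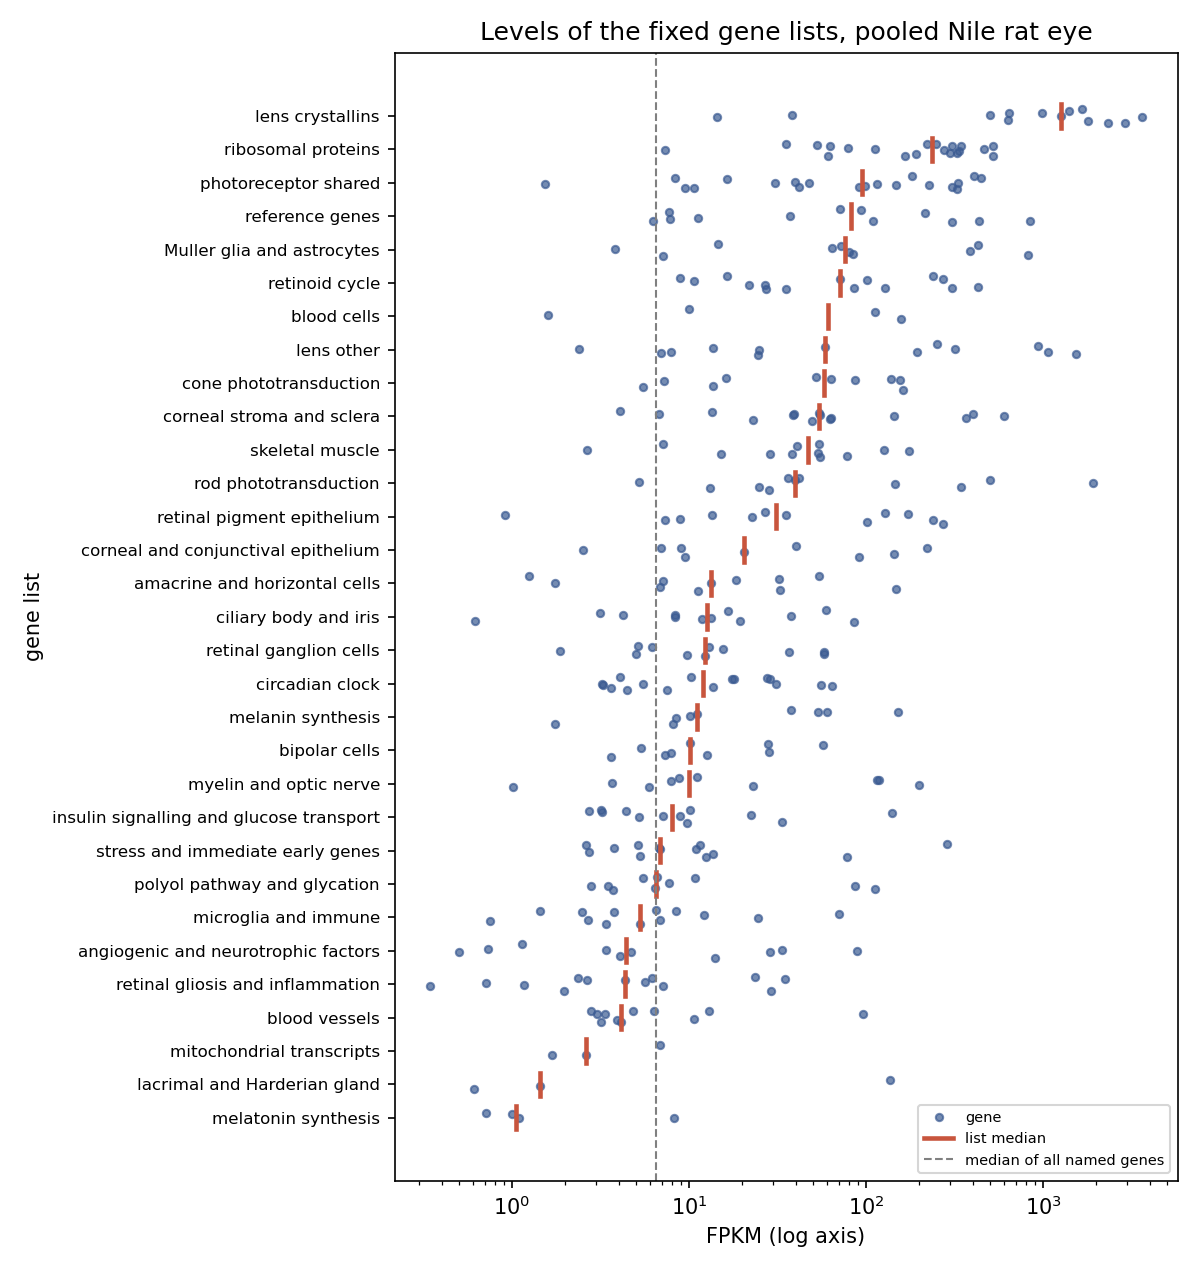
FPKM of each measured gene (points, log axis) in the fixed gene lists with at least 3 measured members, with the list median (red bar) and the median of all named genes (dashed line, 6.50 FPKM), in the single pool. Lens crystallins have the highest median, 1263 FPKM, and the 4 measured genes of the melatonin synthesis list, which include the dopamine receptor Drd4, the lowest, 1.05 FPKM.

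The balance of cone to rod transcripts was read from pairs of homologous phototransduction genes within the pool. Of the 11 pairs, 8 could be measured; Gngt2, Arr3 and Pde6b were not analysed here because no transcript carried their symbol. The rod member was higher in 7 of the 8 pairs, and the median log2 ratio of cone to rod was -1.18 [-1.21 to -1.14], a level 2.27-fold higher for the rod gene. Summed over the pairs, rod genes were 4.33-fold above cone genes. This ratio of sums is weighted toward the most abundant genes and includes the pair not reported here. The cyclic nucleotide-gated channel subunit Cnga1 of rods was 6.60-fold [6.23 to 6.98] above the cone subunit Cnga3 (36.2 against 5.49 FPKM). The rod transducin Gnat1 was 2.48-fold [2.45 to 2.52] above the cone transducin Gnat2 (344 against 139 FPKM), and the exchanger Slc24a1 was 2.46-fold [2.36 to 2.57] above Slc24a2 (39.7 against 16.1 FPKM). Smaller ratios were found for Cngb1 over Cngb3, 2.09-fold (28.5 against 13.6 FPKM), for the inhibitory phosphodiesterase subunit Pde6g over Pde6h, 1.69-fold (146 against 86.5 FPKM), and for Gnb1 over Gnb3, 1.26-fold (196 against 156 FPKM). Gnb1 is expressed in many cell types besides rods. The single pair with a higher cone member was Pde6c over Pde6a, the catalytic phosphodiesterase subunits, at 52.2 against 24.9 FPKM (log2 ratio 1.07 [1.02 to 1.11]).

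Gnat1, Gnb1, Cnga1 and Slc24a1 were above their cone partners in every setting, whether transcripts of a gene were summed, averaged by length or reduced to the highest. For Gnat1, Gnb1, Cnga1 and their partners these ways give the same value by construction, since a single transcript carried each gene. Slc24a2, the partner of Slc24a1, had several transcripts. The direction of 3 pairs depended on the setting. With a length-weighted mean, Pde6c over Pde6a was -0.072, Pde6h over Pde6g was 0.11 and Cngb3 over Cngb1 was 0.50 on the log2 scale.

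Of the cone opsins, the middle-wavelength opsin Opn1mw (162 FPKM [157 to 167]) was 2.54-fold above the short-wavelength opsin Opn1sw (63.7 FPKM [60.7 to 66.9]), a log2 ratio of 1.35 [1.26 to 1.43]. Opn1mw rested on 1 transcript of 378 nt, and Opn1sw was the sum of 3 transcripts of up to 919 nt, each named from a different species. The log2 ratio was 2.12 with the highest transcript of each gene and 3.19 with a length-weighted mean.

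**Figure D2:**
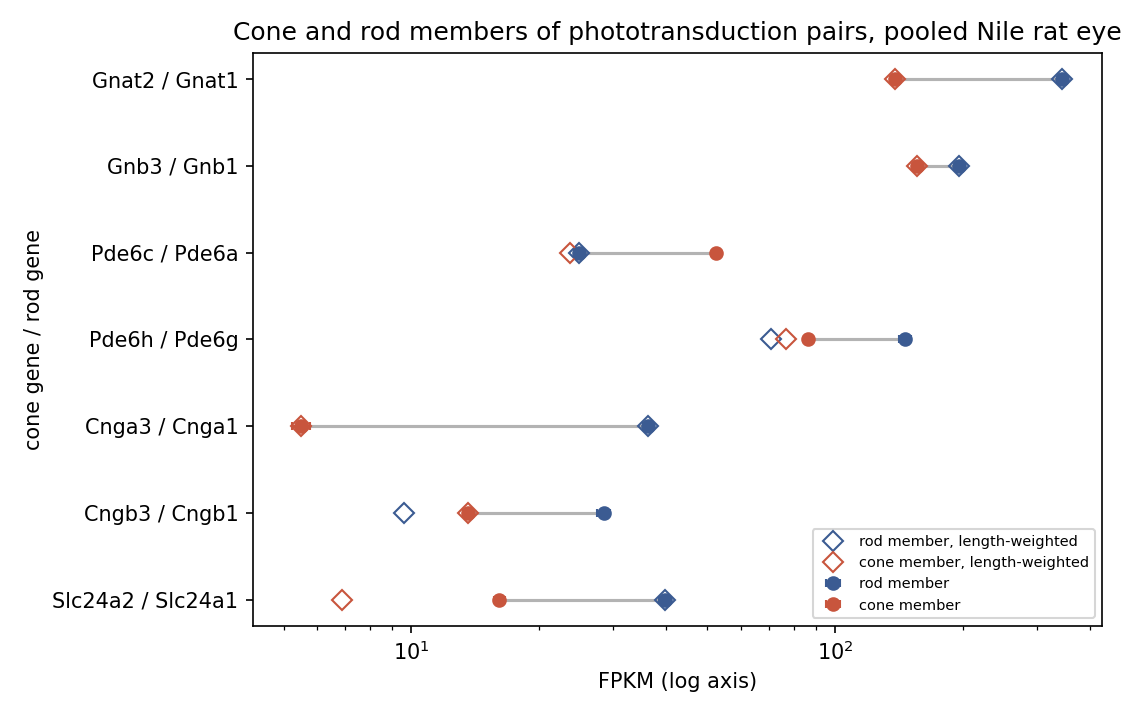
FPKM (log axis) of the cone (red) and rod (blue) member of 7 pairs of homologous phototransduction genes in the single pool. Filled points are sums over a gene's transcripts with 95% counting intervals, mostly smaller than the points, and open diamonds are length-weighted means. By sums the rod member is higher in each pair shown except Pde6c and Pde6a, at 52.2 and 24.9 FPKM.

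Genes of the inner retina were present at lower levels than photoreceptor genes. All 9 measured bipolar cell genes were detected, with a median of 10.2 FPKM and with Gng13 (57.0 FPKM) and Scgn (28.1 FPKM) highest. The metabotropic glutamate receptor Grm6 of ON bipolar cells was at 7.35 FPKM. All 11 measured genes of amacrine and horizontal cells were detected, led by Calb2 (calretinin, 148 FPKM) and the GABA-synthesizing enzyme Gad1 (54.1 FPKM), while Th, the dopamine-synthesis enzyme, was at 1.75 FPKM. All 11 measured genes of retinal ganglion cells were detected, with Nefl at 58.3 FPKM, Thy1 at 57.6 FPKM and the photopigment melanopsin (Opn4) at 6.21 FPKM [5.81 to 6.62]. The medians of these 3 lists lay above those of 81.6%, 94.7% and 92.4% of random lists, short of the 95% mark. Genes of Müller glia and astrocytes were higher, with a median of 76.2 FPKM, above all 10000 random lists. Apoe, Rlbp1 (a retinal carrier protein, 432 FPKM) and Clu (386 FPKM) led this list, and Gfap was at 7.14 FPKM.

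The retinal pigment epithelium contributed measurable RNA. Of 12 measured genes, 11 were detected, with a median of 35.4 FPKM and the visual cycle isomerase Rpe65 (238 FPKM) among the highest, and Mertk was at 0.912 FPKM. Genes of the retinoid cycle, which share members with other fixed lists, were all detected (15 of 15, median 71.7 FPKM), with Rlbp1 and Rbp3 highest. All 9 measured genes of melanin synthesis were detected, with Tyrp1 at 152 FPKM and Mlana at 60.2 FPKM. The list's median of 11.1 FPKM was above that of 85.8% of random lists.

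Genes of the ocular coats and anterior segment were also abundant. All 15 genes of corneal stroma and sclera were detected, with a median of 54.0 FPKM, led by the proteoglycan decorin (Dcn, 603 FPKM) and Sparc (403 FPKM), and Kera, a keratan sulfate proteoglycan of the cornea, was at 55.1 FPKM. Of the epithelial list, 9 of 14 genes carried a symbol and all 9 were detected with a median of 20.5 FPKM, with Tkt (220 FPKM) and Krt4 (144 FPKM) highest and the cornea-specific keratin Krt12 at 91.0 FPKM. Of the ciliary body and iris list, 11 of 12 measured genes were detected, with Myoc (myocilin, 85.0 FPKM) and Car2 (carbonic anhydrase, 59.2 FPKM) highest. The median of the 11 detected genes, 13.4 FPKM, was above that of 95% of random lists.

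Genes of adjoining tissue were present in the same pool. All 12 measured skeletal muscle genes were detected, with a median of 47.1 FPKM, led by Tnnc2 (174 FPKM) and Mb (myoglobin, 127 FPKM). Of the blood cell list, 4 of 13 symbols were measured, with a median of 60.9 FPKM. The globins Hba-a1 and Hbb-b1 were highest, at 158 and 112 FPKM, on transcripts whose symbols differed between species and whose fragments can be shared between globin copies. Among myelin genes, all 10 were detected, with Mal at 199.97 FPKM and Mbp at 118 FPKM. Their median of 9.98 FPKM was above that of 80.6% of random lists, and Mal is also made by epithelia. Of the lacrimal and Harderian gland list, 3 of 12 genes carried a symbol: Aqp5 was at 136 FPKM, while Ltf was at 1.43 FPKM and Scgb2a2 at 0.610 FPKM. Aqp5 is also a water channel of the cornea. Blood vessel genes had a median of 4.12 FPKM, above only 6.66% of random lists, with Rgs5 (96.0 FPKM) and Kdr (12.9 FPKM) highest. Of 13 measured immune genes, 12 were detected, with a median of 5.90 FPKM, above 29.3% of random lists, and Cd74 (70.0 FPKM) and Lyz2 (24.4 FPKM) were highest.

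Among pathways, 16 of 20 circadian clock symbols were measured and all 16 were detected, with a median of 11.97 FPKM, above 94.5% of random lists. The output factors Dbp (64.0 FPKM) and Tef (55.8 FPKM) were highest, and 9 of the 16 genes reached 10 FPKM. Of the core genes, which also include Cry2, Arntl, Clock, Per1, Per2, Per3 and Cry1 lay between 3.22 and 5.49 FPKM. With 1 pool, levels at different times of day could not be compared. The melatonin synthesis list had 4 of 7 symbols measured and a median of 1.10 FPKM over the 3 detected. It was the single list with a median below that of at least 95% of random lists. Drd4, a dopamine receptor, was at 8.19 FPKM and Ddc at 1.10 FPKM. Aanat, the rate-limiting enzyme of melatonin synthesis, rested on 1 transcript of 184 nt at 0.711 FPKM [0.316 to 1.37]. Aanat was therefore not among the 3 detected members, and no transcript carried the symbols Asmt, Mtnr1a or Mtnr1b. The rank of the list does not cover these genes and was not read as low melatonin synthesis. The polyol and glycation list had a median of 6.53 FPKM, with Hk1 (112 FPKM) and Glo1 (86.8 FPKM) highest. No transcript carried the list's symbols for aldose reductase, Akr1b1 and Akr1b3, while Akr1b4, an older rat symbol for that enzyme and outside the list, was at 108 FPKM. The insulin and glucose transport list had a median of 8.05 FPKM, with the glucose transporter Slc2a1 at 139.6 FPKM and Txnip at 33.6 FPKM. Among angiogenic and neurotrophic factors, 8 of 10 measured genes were detected at a median of 9.32 FPKM, with Vegfb (88.6 FPKM), Serpinf1 (33.5 FPKM) and Vegfa (28.6 FPKM) highest. The medians of these 3 lists lay above 40.9%, 63.9% and 62.9% of random lists.

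Genes of stress and gliosis were not high as classes. The median of the 13 measured stress and immediate early genes was 6.89 FPKM, above 46.2% of random lists, although Hspb1 (288 FPKM) and Dnajb1 (78.5 FPKM) were high and Fos was at 5.12 FPKM. Of 13 measured genes of gliosis and inflammation, 11 were detected, with Stat3 (29.0 FPKM) among the highest, and the median of these 11 was 5.66 FPKM, above 26.3% of random lists. Ribosomal protein genes (20 of 22 measured, median 235 FPKM, with Rps6 at 525 and Rps14 at 521 FPKM) and reference genes (12 of 15 measured, median 82.5 FPKM, with Gapdh and Ppia at 849 and 435 FPKM) lay above all 10000 random lists. Of the mitochondrial list only 3 names matched, Cox2, mt-Nd4 and Cytb, at 6.85, 2.62 and 1.69 FPKM, while the transcript named cytochrome b stood at 1392 FPKM. The list was therefore not read as a measure of mitochondrial RNA. No transcript carried a symbol of the sex-linked list.

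Lens crystallins were compared with photoreceptor genes as a measure of tissue make-up. The summed crystallins stood 2.66-fold above the summed rod, cone and shared photoreceptor genes, a log2 ratio of 1.41 [1.41 to 1.42]. The median log2(FPKM + 1) was higher by 4.57 in the crystallins. The ratio of sums turned to -0.24 when transcripts of under 500 nt were left out, which removed Crygb, Cryab, Crygc, Cryba2, Crybb1, Crygd and Cryga. The 249 nt transcript of Cryaa, at 1158 FPKM, was left out as well. The ratio was -0.41 with fragments in place of FPKM, so the direction depended on short transcripts and on the division by length.

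The named genes covered a part of the sequenced RNA. Transcripts with a symbol held 47.2% of fragments and 18.0% of FPKM, and had a median length of 2156 nt. Transcripts without an ortholog held 47.0% of fragments and 77.8% of FPKM, and had a median length of 342 nt. Shares of FPKM given above are therefore shares among named genes: of the FPKM of all transcripts the crystallins held 1.30%.

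**Figure D3:**
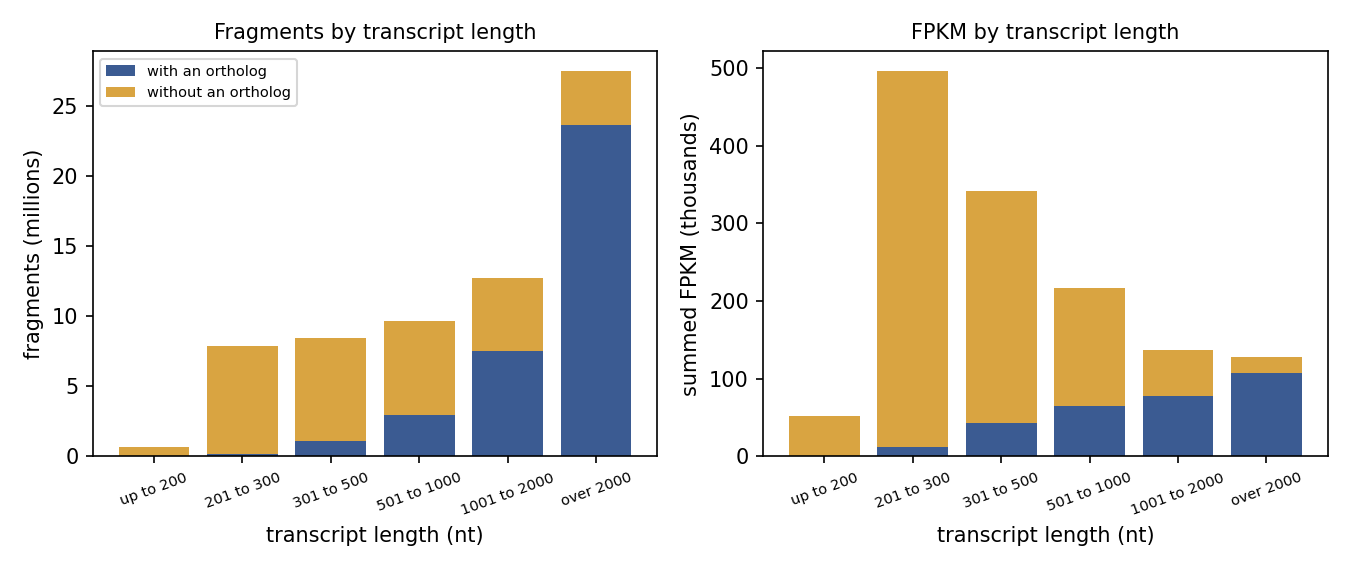
Fragments (left) and summed FPKM (right) of all 124439 transcripts by transcript length in nt, split into transcripts with an ortholog (blue) and without one (yellow). Transcripts over 2000 nt hold 41.2% of fragments and 9.31% of FPKM, while those of over 200 and up to 300 nt hold 11.8% of fragments and 36.2% of FPKM.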

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

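Of the tests in this part, the one on transcripts of at least 1000 nt was chosen after its result was seen, and the other test was written before. With 1 pool, samples could not be compared with one another.

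Large signals lay in transcripts that none of the comparisons used. Transcripts without an ortholog held 47.0% of fragments, and transcripts with an ortholog but no symbol held a further 5.72%. The most abundant transcript without an ortholog, tx0115510 in the table, reached 21307 FPKM on 276855 fragments and 200 nt. The transcript with an ortholog and no symbol that held most fragments, tx0021015, reached 3161 FPKM on 295525 fragments and 1439 nt. All 20 transcripts of highest FPKM lacked an ortholog, at lengths of 200 to 555 nt, as did 89 of the 110 transcripts at FPKM 1000 or above. Only 15.4% of all transcripts had an ortholog, so these counts alone do not show an excess.

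Transcripts without an ortholog held most of the FPKM, 77.8%, but 47.0% of fragments, which are not divided by length. Their share was thus a majority only after the division of fragments by transcript length. They were also most of the transcripts, since only 15.4% of all transcripts had an ortholog, so their number enters this share as well. The test on long transcripts cannot separate number from length by itself. Among transcripts of at least 1000 nt those without an ortholog held 29.8% of FPKM. They were also only 47.0% of these transcripts, so this share does not isolate the division. The tables argue against a general excess of each short transcript without an ortholog: over 200 and up to 500 nt their median was 0.708 FPKM, below the 0.845 FPKM of transcripts of that length with one (66032 against 2202 transcripts, 95% bootstrap interval of the difference -0.19 to -0.10). Whether the most abundant ones are pieces of crystallin, mitochondrial or ribosomal RNA stays open, because the sequences were not analysed here, and no biological explanation was tested.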

How the results depend on the processing

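No paired analysis was possible because the table holds 1 pool and 1 group. Leaving out samples, the spread between samples, the agreement between samples and names from the other ortholog table were not run, for want of values per sample and of symbols. The count of detected genes, 13037, was 8366 at a threshold of 5 and lay within 1.5 times the main count under the other 7 alternatives. The cone to rod ratio stayed below 0 in all 7 alternatives run: -1.13 with a pseudocount of 1, -2.12 from summed levels, -0.998 with the highest transcript only, -0.82 with length-weighted means and -1.07 with transcripts of at least 500 nt. The M to S opsin ratio stayed above 0, at 2.12 with the highest transcript and 3.19 with length-weighted means, and Opn1mw itself dropped out with transcripts of at least 500 nt. The lens to photoreceptor ratio was 4.57 as a difference of medians, 1.64 with the highest transcript, 1.84 with length-weighted means, 1.51 with agreeing symbols and -0.24 with transcripts of at least 500 nt, where the shorter crystallin transcripts were left out by construction, and -0.41 with fragments in place of FPKM, which are not divided by length by construction. Of 47 values for single pairs 42 kept their sign, some of them by construction, where a single transcript carried each gene of the pair. Those that reversed were Pde6c over Pde6a, -0.072 with length-weighted means; Pde6h over Pde6g, 0.056 with the highest transcript, 0.11 with length-weighted means and 0.44 with transcripts of at least 500 nt; and Cngb3 over Cngb1, 0.50 with length-weighted means. These genes, or their partners, have 2 transcripts each, and the cause was not tested. The number of lists above at least 95% of random lists was 14 to 17 against 15. Of 247 list shares 194 stayed within 1.5 times the main value and the other 53 lay between 0.0463 and 2.08 times it, lowest for blood cells with transcripts of at least 500 nt. Over all transcripts every share was 0.180 times the main value by construction. At this depth FPKM 1 on 1000 nt rests on 65.0 fragments, and shorter transcripts of that level on fewer.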

Other observations

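The tests in this part were written before their results were seen, while the gene families described were chosen after the data were seen.

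The median was 4.86 FPKM for GABA-A receptor subunits, 3.70 FPKM for glycine receptor subunits, 4.68 FPKM for ionotropic glutamate receptor subunits, 4.57 FPKM for connexins and 11.6 FPKM for non-visual opsins, with no test against other genes. Of 13 GABA-A receptor subunits 12 reached FPKM 1, with Gabrr2 at 10.8 FPKM. Glrb (16.4 FPKM) led 5 glycine receptor subunits, and the kainate receptor subunit Grik1 (27.3 FPKM) led 7 ionotropic glutamate receptor subunits, above Gria2 at 9.07 FPKM. The synaptic vesicle protein Syt1 stood at 65.4 FPKM. Among connexins, GJA1 (39.9 FPKM) and Gjd2 (25.4 FPKM), the neuronal connexin, were highest, and the lens connexin Gja3 was at 13.6 FPKM. The level of Gjd2 rested on 1 transcript whose symbols differ between species. Among non-visual opsins, RRH (172 FPKM) and Rgr (128 FPKM), both of the pigment epithelium, were far above OPN3 (11.6 FPKM) and Opn4 (6.21 FPKM).

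All 6 peroxiredoxins were above 10 FPKM, led by Prdx2 (186 FPKM), and 2 of 6 glutathione peroxidases were, led by Gpx4 (74.1 FPKM), with a median of 8.02 FPKM. Among glutathione S-transferases, 11 of 15 were above 10 FPKM, led by Gstp2 (143 FPKM, on a transcript whose symbols differ between species) and Gsta4 (106 FPKM). Keratins with a symbol were led by Krt75 (189 FPKM), above the corneal Krt12 (91.0 FPKM), while no transcript carried the symbols Krt3, Krt5 or Krt15. Water channels were led by Aqp5 (136 FPKM), Aqp3 (99.8 FPKM) and Aqp1 (66.7 FPKM). Eno2, the neuronal enolase, was at 141 FPKM against 2.61 FPKM for Eno1, a difference that rests on 1 named transcript of each. Ldha stood at 731 FPKM.

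Several genes were split into transcripts that each carried the symbol from a different species, as Opn1sw was. Of the 1380 genes with several transcripts, 60.1% had no species column that named more than 1 of them, above the highest of 1000 shuffles of the columns (41.9%, median 38.6%). This is consistent with each species' transcript having been matched to a single Nile rat transcript, so that pieces of 1 mRNA may be named from different species. In that case summed FPKM would overstate such genes, and length-weighted means would be closer. Overlapping isoforms stay open, since the sequences were not analysed here.

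Symbols differed between species on 2586 named transcripts. In 97.8% of them at most 1 of the symbols was a current Nile rat symbol, which is consistent with older symbols for the same gene but does not show that the symbols name 1 gene. Of the 58 transcripts with different symbols of current protein-coding genes, 34.5% (20) had symbols that lie within 2 genes of each other in the Nile rat RefSeq annotation (assembly mArvNil1.pat.X), above the highest of 1000 shuffles of the pairs (6.90%). The transcript named Srprb and TF is such a case, since these are adjacent genes. Neighbouring genes meeting on 1 transcript is a candidate explanation for that part; families of adjacent paralogs were not separated from it.

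The fragments of all transcripts summed to 66703011, which is 2.67% above the mapped total stated in the file.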
